A study of Mus musculus with 6 samples.

How the data were processed

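RNA was taken from whole lung lobes of mouse embryos at E18.5, dissected before breathing and snap-frozen; per the labels' protocols, polyadenylated RNA was made into strand-specific libraries (NEBNext Ultra II Directional kit) and read as 75 bp single reads on an Illumina NextSeq. Per the submitters' processing notes, reads were handled with bcl2fastq 2.19.1 and GSNAP on mm10, and featureCounts 1.6.3 and DESeq2 1.24.0 were used. The deposited count table holds raw counts per gene: per the file headers it was made with featureCounts in reverse-stranded mode (setting 2) with a mapping quality of at least 1, and its name carries Ensembl release 98. All of its values were whole numbers. It has 55513 rows, of which 92 are ERCC spike-in names that hold 1 read in all and were left out. Because reads that map equally well to several places are mostly removed by a mapping quality filter, genes with near-identical copies are uncertain, whereas strand-aware counting keeps antisense genes apart. The second deposited table holds a normalized signal, counts divided by 1 size factor per library, rounded to 1 decimal by the authors. Multiplied by that factor, 100% of its 24521 genes gave back the count table within 0.1 read in each of the 6 libraries, and none of its genes has fewer than 11 reads in total. It supplied gene symbols and served as an alternative input; symbols of the other 30900 genes were looked up in a reference table by gene identifier. All coordinates are those of the count table.

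Libraries were assigned to wild type (3) and Mll3 knockout (3) by the genotype label, and replicate numbers follow the order of the samples only. Library totals ran from 20158689 to 23305306 reads, so a gene at 1 CPM has about 20 reads per library. Counting error is therefore not small for named genes near that level, such as Slc10a5 (0.53 CPM in knockout lungs) and Tafa2 (0.68 CPM in wild-type lungs). The 34615 genes with a read were reduced by filterByExpr to 19042, which held 99.8 to 99.9% of the reads. The main test was edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3) with TMM factors, robust dispersion and genotype as the only term, with Benjamini-Hochberg adjustment and a threshold of 0.05. Standard errors are the absolute log2 fold change divided by the square root of F. Means and SDs are of CPM after TMM scaling, n = 3 per genotype.

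Gene lists (49) of lung cell types, of tissues that dissection may carry along, and of pathways were fixed before the data were examined. Camera (limma 3.58.1) compared each list of at least 5 tested members with the other genes on log2 CPM (prior count 2) with a preset correlation of 0.01 between genes, and was repeated with a correlation estimated from the data; fry tested whether members move on balance one way. Of 45 lists tested, 18 passed with the preset correlation, 0 with an estimated correlation and 0 in fry. Members were counted as having risen or fallen over all genes tested and, separately, adjusted over the list alone. Named genes followed a rule set at the same time: Kmt2c, Kmt2d, Kdm6a, Sftpa1, Sftpb, Sftpc, Sftpd, Abca3, Ager, Hopx, Aqp5 and Pdpn; up to 12 genes with the largest rise and 12 with the largest fall among those past the threshold with a mean of at least 1 CPM in the higher genotype and no overlap between genotypes, leaving out predicted models; and up to 4 members with the lowest p in each list described.

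The sample titles carry 2 number prefixes whose meaning is not stated. The labels state no covariate, so the planned model held genotype only and the prefix entered only as an alternative. Calculated later and without bearing on that choice, deviations from the genotype means were correlated between libraries of different genotype. They correlated at −0.11 to 0.25 in the 4 pairs of the same prefix (mean 0.07), and at −0.28 to 0.30 in the 5 pairs of different prefix (mean −0.05). Deviations cancel within each genotype, so the 2 means are tied to each other and are not independent measurements. Other alternatives were DESeq2 1.42.0, limma voom, other scaling (size factors of the DESeq2 kind, library size only), no or a stricter filter (1 CPM in 3 libraries), each library left out in turn, a term for the split of libraries by Xist and Y-linked reads, leaving out erythroid genes or chromosomes X and Y, stricter thresholds, and limma on the normalized signal.

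The tests were tried on simulated counts for the 19042 genes, drawn with the means, library sizes and dispersions of these libraries, with 200 genes of at least 1 CPM changed in each of 5 rounds. edgeR recovered 47.2% of genes changed 1.5-fold, 82.4% of those changed 2-fold and 95.2% of those changed 3-fold, and 6.95% of its calls were false. DESeq2 recovered 78.4% of all changed genes with 15.2% false calls, edgeR 74.8%, and limma voom 70.5% with 6.41% false calls. A list shifted by −0.5 was found by camera in 3 of 3 rounds and 0 of 220 tests of other lists passed. The simulated genes vary independently of each other, which real genes do not, so this says nothing about false list calls in the real libraries.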

Results

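Gene expression was measured by RNA sequencing in whole lungs of mouse embryos at E18.5, shortly before birth, when alveolar type 1 and type 2 cells have separated and surfactant is being made. Of the 6 libraries, 3 came from wild-type lungs and 3 from lungs homozygous for a knockout allele of Mll3, the histone H3 lysine 4 methyltransferase encoded by Kmt2c. The count table held between 20158689 and 23305306 reads per library, and 19042 genes had enough reads to be tested. Read counts of libraries within a genotype differed by more than sampling noise, with a chi-square over its degrees of freedom of 9.27 to 22.97, so no library was a copy of another. Knockout 3 held 59951 Xist reads and 4 reads of the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty, whereas the other 5 libraries held 6 to 27 Xist reads and 7414 to 9300 Y-linked reads. The labels call the samples triplicates, and their titles carry a number as a prefix and a second number that differs between the samples of one prefix. What these numbers stand for is not stated, nor whether the samples came from separate embryos or litters, so p-values measure the spread between these samples.

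Kmt2c (ENSMUSG00000038056, mm10 chromosome 5, 25271798 to 25498783) was read first, since it is the targeted gene. It reached 168 ± 9.58 CPM (SD, n = 3) in wild-type lungs and 158 ± 14.2 CPM (SD, n = 3) in knockout lungs, a log2 fold change of −0.09 ± 0.08 (SE) that did not pass the test (edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 0.74). The labels do not say which part of the gene is deleted, and counts summed over the whole gene cannot check the genotype where transcript from the rest of the locus remains. Kmt2d, which encodes the related methyltransferase MLL4, was at 263 ± 27.2 CPM in wild type and 270 ± 40.2 CPM in knockout lungs (adjusted p = 0.94). Kdm6a, the X-linked H3 lysine 27 demethylase of the same complexes, was at 90.6 ± 5.19 and 107 ± 31.0 CPM (log2 fold change 0.24, adjusted p = 0.74). Knockout 3, the library with Xist reads, had 142 CPM of Kdm6a and knockouts 1 and 2 had 96.6 and 82.1. With a term for the Xist and Y-linked split the log2 fold change was −0.02. Knockout 3 is alone on one side of that split, so this value compares knockouts 1 and 2 with wild type.

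In the knockout lungs, 12 genes were higher and 58 were lower than in wild type at an adjusted p under 0.05. The falls were led by Ifit1, an interferon-induced inhibitor of translation, which went from 10.5 ± 1.46 to 2.94 ± 0.97 CPM (log2 fold change −1.82 ± 0.23, adjusted p = 0.021). Ifit3 followed at −1.71, then the transporter gene Slc10a5 at −1.67, Alox5, the 5-lipoxygenase of leukotriene synthesis, at −1.59, and the water channel gene Aqp5 at −1.41. The interferon-inducible Ifi203 and the neighbouring pseudogene Ifi203-ps fell by 1.40 and 1.22 on the log2 scale. Both belong to a family of similar copies, so the split of reads between them is uncertain. Pof1b (−1.16), the interferon regulatory factor gene Irf7 (−1.05), the carbonic anhydrase gene Car4 (−1.05), Ly6a (−1.01) and Saa3 (−0.99) completed the 12 deepest falls. Among the 11 rises that met the naming rule, Tafa2 was the steepest, from 0.68 ± 0.12 to 2.31 ± 0.64 CPM (1.76 ± 0.29, adjusted p = 0.043). Slitrk6 rose by 1.10, Angptl4, which encodes an inhibitor of lipoprotein lipase, by 0.99, and the meiotic cohesin gene Rec8 by 0.76. The other rises were Adamts6 (0.66), Egfl6 (0.61), Ccdc136 (0.61), the ephrin receptor gene Epha7 (0.60), Rps6ka6 (0.57), Ctnnd2 (0.54) and Ppp1r14c (0.40). One called gene, Gm47283, is a predicted model annotated on chromosome Y and was set aside by the rule. The 2 genotypes did not overlap in any of the 70 called genes, nor in 17.0% of all tested genes, where chance gives 10%.

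**Figure D1:**
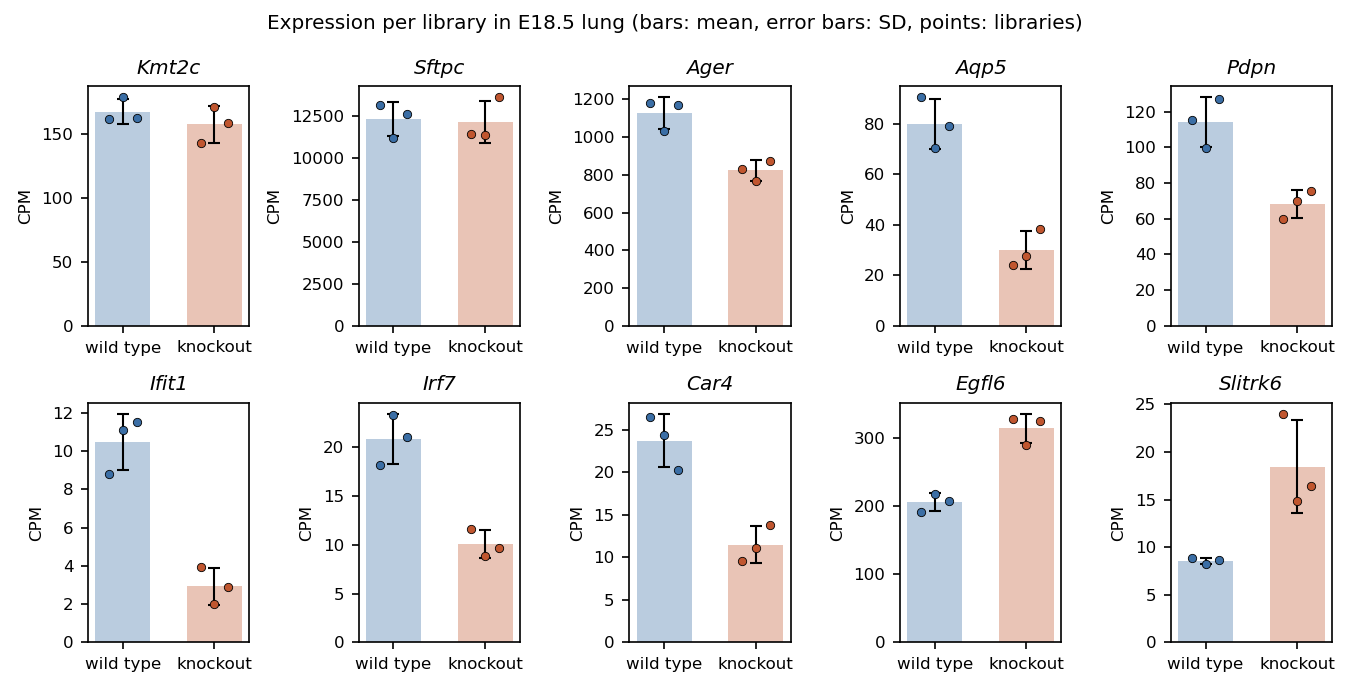
CPM (vertical axes, each from 0) of 10 genes in 3 wild-type and 3 Mll3 knockout lungs, with bars for the mean, error bars for the SD and points for the libraries. Kmt2c and Sftpc overlapped between genotypes, whereas Aqp5 averaged 80.0 CPM in wild type and 30.1 CPM in knockout lungs and Egfl6 206 and 314 CPM, with no overlap.

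These counts depended on the model and on single libraries. With the number that prefixes the sample titles as a term (one prefix on wild type 1, wild type 2 and knockout 1, the other on the rest; its meaning is not stated), 142 genes were higher and 483 lower, including all 70. DESeq2 called 62 higher and 295 lower, and limma voom 0 higher and 8 lower. A term for the Xist and Y-linked split gave 4 and 28, of which 22 were among the 70. Knockout 3 is alone on one side of that split, so the term cannot separate sex from this 1 library. The genotype difference in that model rests on knockouts 1 and 2 against wild type. Without wild type 1, 3 genes remained, and without wild type 2 or wild type 3 none did in edgeR, although 1954 and 1629 genes had an unadjusted p under 0.05 and DESeq2 still called 309 and 217. Without knockout 1, 2 or 3, edgeR called 41, 11 and 27 genes.

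Among the lists past the camera threshold, interferon-response genes had the lowest median. All 14 tested members were lower in knockout lungs, with a median log2 fold change of −0.98. Over all genes tested, 4 of them fell and 10 did not pass, and adjusted over the list alone all 14 fell. In the model with the title prefix as a term 6 of them fell, and DESeq2 without that term called 12 lower and 0 higher. Usp18, which restrains signalling from the type I interferon receptor, went from 22.8 ± 2.19 to 12.1 ± 1.38 CPM (adjusted p = 0.021). Irf7, a transcription factor that amplifies interferon production, went from 20.8 ± 2.56 to 10.05 ± 1.45 CPM (adjusted p = 0.021), and Ifit3 from 5.15 ± 1.598 to 1.57 ± 0.34 CPM (adjusted p = 0.039). The list passed camera with a preset correlation (adjusted p = 1.25e-16). It did not pass with one estimated from the data (adjusted p = 0.49 with an estimated correlation) or in fry (adjusted p = 0.16). The median difference was −0.65 within one title prefix, where knockout 1 is the only knockout. It was −1.21 within the other, where wild type 3 is the only wild type. Both are parts of the genotype comparison above and no separate support for it.

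Alveolar type 1 genes, markers of the flat cells that form the gas-exchange surface, were lower as well. Of 18 tested members 16 were lower, 3 fell over all genes tested, 15 did not pass, and adjusted over the list alone 16 fell, with a median log2 fold change of −0.45. Aqp5, the type 1 cell water channel (mm10 chromosome 15, 99590782 to 99594829), went from 80.0 ± 10.1 to 30.1 ± 7.58 CPM (−1.41 ± 0.18, adjusted p = 0.042). Pdpn, the T1alpha membrane glycoprotein (mm10 chromosome 4, 143267431 to 143299564), went from 114 ± 13.8 to 68.3 ± 7.96 CPM (−0.74 ± 0.11, adjusted p = 0.039), and Clic5 from 963 ± 24.8 to 646 ± 72.4 CPM (−0.58 ± 0.09, adjusted p = 0.042). Gprc5a, at 514 ± 19.6 and 377 ± 32.0 CPM, did not pass (adjusted p = 0.055; 0.022 with the title prefix as a term). Nor did Ager, at 1128 ± 82.7 and 824 ± 55.7 CPM (adjusted p = 0.074), or Hopx, at 410 ± 37.7 and 309 ± 25.4 CPM (adjusted p = 0.11). With the title prefix as a term Ager and Hopx passed at 0.032 and 0.028, and 15 of the 18 members fell. DESeq2 without that term called 15 members lower and 0 higher. The list passed camera (adjusted p = 1.93e-13), but not with an estimated correlation (adjusted p = 0.49 with an estimated correlation). The median difference was −0.55 within one prefix and −0.46 within the other.

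Alveolar type 2 and surfactant genes showed no common direction. Of 20 tested members, 1 rose, 0 fell and 19 did not pass (7 had an unadjusted p under 0.05, and DESeq2 called 3 higher and 1 lower); adjusted over the list alone 4 rose and 1 fell. Their median log2 fold change was 0.05, their mean −0.07, and camera pointed upward without passing (adjusted p = 0.48), so that mean and median differ in sign. Sftpc, the most abundant of the surfactant protein genes, was at 12347 ± 1003 CPM in wild type and 12164 ± 1270 CPM in knockout lungs (−0.02 ± 0.12, adjusted p = 0.97). Sftpb (0.14), Sftpa1 (−0.02) and the lipid transporter gene Abca3 (0.16) did not pass, and neither did Sftpd at 265 ± 54.8 and 165 ± 52.1 CPM (−0.69 ± 0.30, adjusted p = 0.52; 0.033 with the title prefix as a term). Egfl6, an extracellular matrix protein, rose from 206 ± 13.5 to 314 ± 21.1 CPM (adjusted p = 0.021). The aspartic protease gene Napsa (0.42, adjusted p = 0.057), Etv5 (0.45, adjusted p = 0.072) and the lung transcription factor gene Nkx2-1 (0.25, adjusted p = 0.27) were higher without passing. The model with the title prefix had 3 members that rose, Egfl6, Napsa (adjusted p = 0.023) and Etv5 (0.032), and 2 fell, Sftpd and Chil1 (0.012), a chitinase-like gene at −1.09 and an adjusted p of 0.27 without the term.

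**Figure D2:**
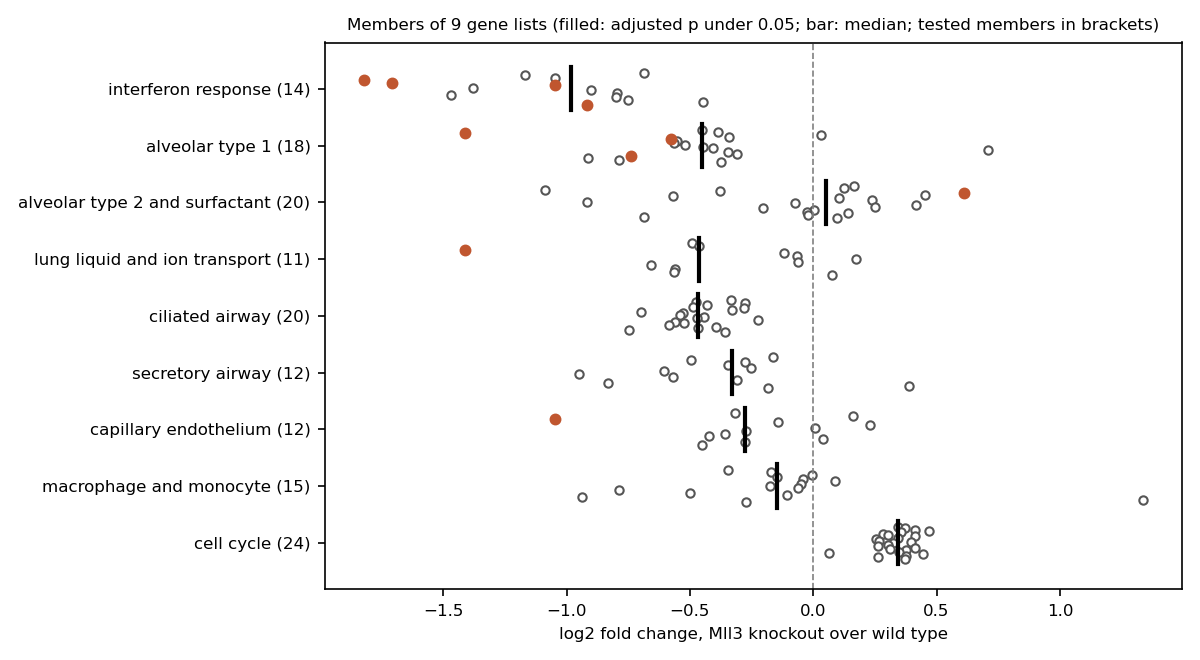
Log2 fold change of knockout over wild type (horizontal axis) for each tested member of 9 gene lists (rows, with the number of members in brackets); filled points had an adjusted p under 0.05 over all genes and vertical bars mark medians. All 14 interferon-response members lay below 0 with a median of −0.98, the alveolar type 1 median was −0.45 and the alveolar type 2 median 0.05.

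Ciliated airway genes were lower in point estimate for all 20 tested members, with a median log2 fold change of −0.47, but 0 passed over all genes or adjusted over the list alone in edgeR; 3 had an unadjusted p under 0.05 and DESeq2 called 0. Foxj1, the regulator of motile cilia, was at 65.3 ± 14.3 and 48.0 ± 5.87 CPM (adjusted p = 0.38) and Tmem212 at 9.09 ± 3.21 and 5.43 ± 1.26 CPM (adjusted p = 0.36). With the title prefix as a term 16 of the 20 fell, and the adjusted p of Foxj1 was 0.0095. The list passed camera (adjusted p = 2.1e-06; adjusted p = 0.63 with an estimated correlation), its median being −0.22 without wild type 3 and −0.27 without knockout 1. Secretory airway genes had a median of −0.33 over 12 members, none of which passed (3 at an unadjusted p under 0.05, 1 in DESeq2, 4 with the prefix term). The list passed camera at an adjusted p of 0.0014 (adjusted p = 0.63 with an estimated correlation), with a median of −0.14 without wild type 3. Its members with the lowest p were Gabrp, at 15.1 ± 3.13 and 7.85 ± 2.34 CPM (adjusted p = 0.20), and Hp, at 262 ± 67.4 and 177 ± 24.0 CPM (adjusted p = 0.39).

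Among 11 genes of lung liquid and ion transport, Aqp5 fell and 10 did not pass. Adjusted over the list alone 3 fell. These were Aqp5, the second water channel gene Aqp1 (605 ± 64.3 and 430 ± 23.6 CPM, adjusted p = 0.062 over all genes) and Scnn1g, a subunit of the epithelial sodium channel (103 ± 9.91 and 69.4 ± 10.5 CPM, adjusted p = 0.11). Adding the title prefix as a term gave 4 that fell: Aqp5, Aqp1 (adjusted p = 0.016), Scnn1g (0.0098) and Scnn1b (0.0081). The median was −0.46 and the list passed camera (adjusted p = 0.0023; adjusted p = 0.63 with an estimated correlation), with medians of −0.12 without wild type 3 or without knockout 1.

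Among endothelial lists, the arterial (median −0.03, camera adjusted p = 0.57) and lymphatic (−0.03, adjusted p = 0.45) lists did not pass, and few members of the pan-endothelial and capillary lists passed over all genes. In the pan-endothelial list Calcrl, the receptor of adrenomedullin, fell from 551 ± 26.6 to 370 ± 35.4 CPM (−0.58 ± 0.09, adjusted p = 0.037), while the other 15 members did not pass; adjusted over the list alone 2 fell. The list median was −0.12 (camera adjusted p = 0.010; adjusted p = 0.63 with an estimated correlation), and the call was lost without wild type 2 (−0.05, adjusted p = 0.20), without knockout 2 (−0.09, adjusted p = 0.13) and with the prefix term (adjusted p = 0.24). In the capillary list Car4, a marker of one capillary cell type, fell from 23.7 ± 3.14 to 11.5 ± 2.18 CPM (adjusted p = 0.035) and 11 members did not pass; adjusted over the list alone 5 fell. Kitl, the stem cell factor gene, was at 361 ± 3.98 and 269 ± 36.5 CPM (adjusted p = 0.11; 0.016 with the title prefix as a term, where 3 capillary members fell). The capillary median was −0.28 (camera adjusted p = 0.010; adjusted p = 0.49 with an estimated correlation).

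Macrophage and monocyte genes had a median of −0.15 over 15 tested members, none of which passed (5 at an unadjusted p under 0.05, 3 in DESeq2), and 3 fell adjusted over the list alone. Fcgr1 was at 7.70 ± 0.62 and 4.45 ± 0.95 CPM (adjusted p = 0.11; 0.035 with the title prefix as a term) and Mrc1 at 60.9 ± 2.73 and 50.4 ± 1.35 CPM (adjusted p = 0.15). Lyz2, a lysozyme gene that type 2 cells also express, was at 961 ± 237 and 502 ± 96.1 CPM (adjusted p = 0.15), and the scavenger receptor gene Marco at 5.59 ± 1.41 and 14.2 ± 6.09 CPM (adjusted p = 0.29). The list passed camera (adjusted p = 0.010; adjusted p = 0.62 with an estimated correlation), but not without wild type 1 (0.065) or knockout 3 (0.065), nor with the prefix term (0.075).

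Cell cycle genes were higher in point estimate for all 24 members, with a median log2 fold change of 0.34, and 0 passed in edgeR over all genes or over the list alone, 5 had an unadjusted p under 0.05 and DESeq2 called 0. Rrm2, a subunit of ribonucleotide reductase, was at 32.0 ± 2.00 and 41.5 ± 8.69 CPM (adjusted p = 0.36), and the replicative helicase genes Mcm4 and Mcm2 were 0.26 and 0.32 higher (adjusted p = 0.37 and 0.38). The list passed camera (adjusted p = 4.5e-06; adjusted p = 0.63 with an estimated correlation). Its median was 0.13 without knockout 1, and the median difference was 0.76 within the prefix that holds knockout 1 and 0.14 within the other. Cartilage genes had a median of 0.26 over 11 members (camera adjusted p = 0.010; adjusted p = 0.49 with an estimated correlation). None passed over all genes (4 at an unadjusted p under 0.05, 1 in DESeq2) and 3 rose adjusted over the list alone. The median ran from 0.21 to 0.61 over the refits without one library (0.61 without wild type 1). Col9a3 was at 1.73 ± 0.26 and 4.26 ± 2.17 CPM (adjusted p = 0.19; 0.027 with the title prefix as a term). Hox genes had a median of 0.10 over 15 members (camera adjusted p = 0.0067; adjusted p = 0.49 with an estimated correlation), with none passing (2 at an unadjusted p under 0.05, 0 in DESeq2), and Hoxb8 at 1.63 ± 0.16 and 2.66 ± 0.28 CPM (adjusted p = 0.23). The Hox call was lost without knockout 1 (0.079).

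**Figure D3:**
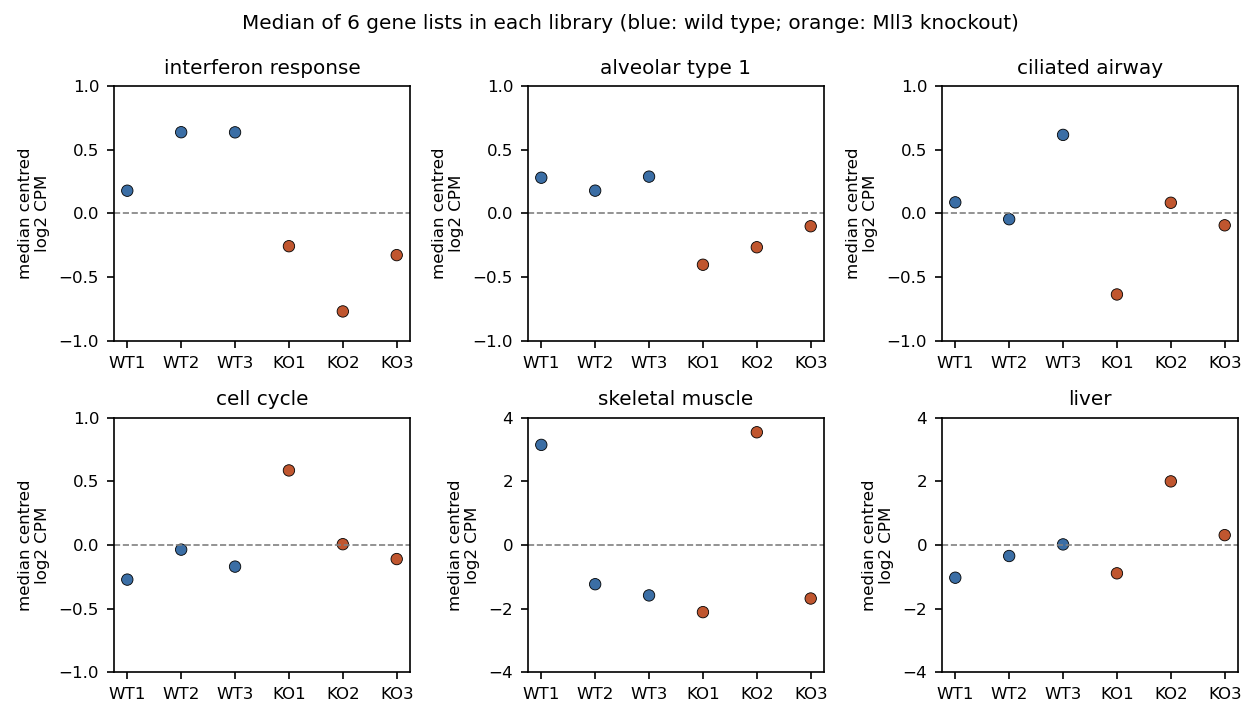
Median log2 CPM of the members of 6 gene lists, centred per gene on the mean of all libraries (vertical axis, with a wider range in the skeletal muscle and liver panels), for wild-type libraries WT1 to WT3 and knockout libraries KO1 to KO3. The interferon-response and alveolar type 1 lists separated the genotypes in all 6 libraries, whereas the skeletal muscle list was high in wild type 1 (3.14) and knockout 2 (3.54).

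The remaining 7 lists past the camera threshold had medians between −0.33 and −0.09. Adventitial fibroblast genes had a median of −0.33 (camera adjusted p = 0.043) and Ly6a as the 1 gene that fell. That median was −0.037 without wild type 1 (adjusted p = 0.29) and −0.11 without knockout 3 (adjusted p = 0.065). Glucocorticoid-responsive genes had −0.12 with Angptl4 rising and Zbtb16 falling (adjusted p = 0.034), and mitochondrially encoded mRNAs −0.13 (adjusted p = 0.044). Elastic fibre and collagen genes had −0.15 (adjusted p = 0.0048), hypoxia and glycolysis genes −0.11 (adjusted p = 0.017), alveolar myofibroblast genes −0.10 (adjusted p = 0.038) and fatty acid and phospholipid synthesis genes −0.09 (adjusted p = 0.010). In the last 4 and among the mitochondrial mRNAs no member passed over all genes in edgeR, with 7, 3, 2, 5 and 0 members at an unadjusted p under 0.05 in that order and 3, 0, 2, 1 and 0 in DESeq2. The edgeR model with the title prefix called 1 member in 3 of them: Fbn2 rose among elastic fibre and collagen genes (adjusted p = 0.048), and Aspn among alveolar myofibroblast genes (0.016) and Chpt1 among synthesis genes (0.010) fell. With the same term Clec3b (0.013) fell beside Ly6a among adventitial genes. Klf9 (0.0077) and Tsc22d3 (0.012) fell beside Zbtb16 among glucocorticoid-responsive genes, and Angptl4 rose. The adventitial fibroblast and alveolar myofibroblast lists lost the camera call with it (adjusted p = 0.087 and 0.15). With an estimated correlation the 7 lists had an adjusted p of 0.56 to 0.70. Zbtb16, a glucocorticoid-induced transcription factor gene, fell from 88.7 ± 6.37 to 60.7 ± 2.06 CPM (adjusted p = 0.021). Eln, the elastin gene, was at 4070 ± 136 and 3013 ± 638 CPM (adjusted p = 0.30). Of all 18 lists past the threshold, 9 passed without any one library and 9, among them 6 of these 7, lost the call without at least 1 library; elastic fibre and collagen was the exception, with medians of −0.23 to −0.12 over these refits.

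Of the 49 lists, 27 were tested and did not pass. Beside alveolar type 2 these were arterial endothelium, lymphatic endothelium, smooth muscle, alveolar fibroblast and lipofibroblast, pericyte, mesothelium, neuroendocrine, basal epithelium, neutrophil, erythroid, platelet and megakaryocyte, heart muscle, skeletal muscle, liver, neuron and Schwann cell, cholesterol synthesis, imprinted genes, circadian clock, immediate early and heat shock genes, hedgehog, Wnt, FGF, BMP and TGF-beta and Notch signalling, subunits of H3K4 methyltransferase complexes and sex-specific transcripts. Their adjusted p ran from 0.070 for immediate early and heat shock genes to 0.997 for skeletal muscle, and the H3K4 methyltransferase complexes, with a median of 0.07 over 17 members, had 0.077. Median, mean and test differed in sign for the neuroendocrine, neutrophil, erythroid, FGF and sex-specific lists. Lymphocyte, thymus, oesophagus and brown fat lists had fewer than 5 tested members and no test. Markers of tissue beside the lung set libraries apart within genotypes. The oesophagus median, over 3 members, was 6.76 in wild type 1 and at most −0.45 in the others. The skeletal muscle median was 3.14 in wild type 1 and 3.54 in knockout 2 but between −2.11 and −1.23 in the others, and the liver median was 2.00 in knockout 2 but at most 0.31 in the others. Without these 2 libraries, an alternative chosen after seeing the data, edgeR called 1 gene higher and 8 lower and 13 lists passed, with medians of −1.005 for interferon response and −0.41 for alveolar type 1.

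A targeted allele can carry flanking sequence from the strain in which it was made, so genes around Kmt2c were compared with those of other chromosomes. None of the 203 tested genes within 10 Mb of Kmt2c was called, against 69 of 17778 on the other chromosomes (Fisher's exact test, two-sided, p = 1). Only 0.39% of genes on the other chromosomes were called, so 0 of 203 cannot tell this region from the rest. In this region 19 of the 203 genes had an unadjusted p under 0.05 in edgeR, against 2043 of all 19042 tested. Neither DESeq2 nor limma voom called any in the region. With the title prefix as a term 7 of the 203 were called, 3.45% against 3.30% on the other chromosomes (Fisher's exact test, two-sided, p = 0.84).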

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

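Of the alternatives, only leaving out wild type 1 and knockout 2 together and combining the title prefix with the sex-transcript term were chosen after the data were seen. Against 12 genes higher and 58 lower in edgeR, DESeq2 called 62 and 295 (70 shared, 2238 genes without an adjusted p), limma voom 0 and 8 (all 8 shared; self-tests at this sample size made calls), no filter 103 and 340, and the title prefix as a term 142 and 483. The sex-transcript split as a term gave 4 and 28, prefix and sex split together 122 and 354, and leaving out wild type 1 and knockout 2 gave 1 and 8. An adjusted p under 0.01 left 0 and 2, an absolute log2 fold change of at least 1 left 2 and 11, glmTreat against 1.2-fold 0 and 3, and limma on the deposited normalized signal 3 and 40. Leaving out each library in turn gave 0 to 5 genes higher and 0 to 36 lower, with fewer samples in each fit; the cause of the other differences was not tested. DESeq2-type size factors gave 14 and 69, library size only 15 and 51, the stricter filter 14 and 74, leaving out erythroid genes 12 and 58 and leaving out chromosomes X and Y 9 and 53; the median of all genes was 0.01 in edgeR and 0.04 with library size only.

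Of 18 lists past the threshold, 0 passed in camera with an estimated correlation and 0 in fry, while leaving out each library gave 13 to 20 lists and every other alternative 13 to 18. One list reversed: basal epithelium, at −1.52 without passing (adjusted p = 0.58), was 1.79 without wild type 1 (adjusted p = 0.013); the centred median of its members is 2.73 in wild type 1 and at most 0.34 in any other library. The median of a list is the same under these 2 tests: alveolar type 1 −0.45, secretory airway −0.33, ciliated airway −0.47, pan-endothelial −0.12, capillary endothelium −0.28, alveolar myofibroblast −0.10, adventitial fibroblast −0.33, macrophage and monocyte −0.15, cartilage 0.26, cell cycle 0.34, fatty acid and phospholipid synthesis −0.0921, glucocorticoid-responsive −0.12, hypoxia and glycolysis −0.11, elastic fibre and collagen −0.15, Hox genes 0.10, interferon response −0.98, mitochondrially encoded mRNA −0.13 and lung liquid and ion transport −0.46. Their adjusted p ran from 0.486 to 0.700 with an estimated correlation and from 0.163 to 0.582 in fry. Without a filter, lists that lost the call were Hox genes (0.0859, adjusted p = 0.0514) and mitochondrially encoded mRNA (−0.13, adjusted p = 0.0582). With the title prefix as a term, lists that lost the call were pan-endothelial (−0.0710, adjusted p = 0.242), alveolar myofibroblast (−0.0942, adjusted p = 0.150), adventitial fibroblast (−0.22, adjusted p = 0.0865) and macrophage and monocyte (−0.15, adjusted p = 0.0753). With the title prefix as a term, lists that gained it were H3K4 methyltransferase complexes (0.0975, adjusted p = 0.0462). With the sex-transcript term, lists that lost the call were alveolar myofibroblast (−0.13, adjusted p = 0.0708), adventitial fibroblast (−0.10, adjusted p = 0.0617) and macrophage and monocyte (−0.0911, adjusted p = 0.0617). With the sex-transcript term, lists that gained it were hedgehog signalling (0.18, adjusted p = 0.00687) and immediate early and heat shock (−0.14, adjusted p = 0.00687). Without wild type 1 and knockout 2, lists that lost the call were pan-endothelial (−0.0875, adjusted p = 0.245), capillary endothelium (−0.17, adjusted p = 0.112), alveolar myofibroblast (−0.0973, adjusted p = 0.0908), adventitial fibroblast (−0.17, adjusted p = 0.103), macrophage and monocyte (−0.17, adjusted p = 0.144), fatty acid and phospholipid synthesis (−0.0553, adjusted p = 0.233), hypoxia and glycolysis (−0.11, adjusted p = 0.101) and mitochondrially encoded mRNA (−0.15, adjusted p = 0.103). Without wild type 1 and knockout 2, lists that gained it were smooth muscle (−0.19, adjusted p = 0.0428), mesothelium (−0.30, adjusted p = 0.0136) and platelet and megakaryocyte (0.40, adjusted p = 0.0363). With both terms, lists that lost the call were pan-endothelial (−0.13, adjusted p = 0.0738), alveolar myofibroblast (−0.10, adjusted p = 0.129), adventitial fibroblast (−0.0951, adjusted p = 0.0973), macrophage and monocyte (−0.10, adjusted p = 0.129) and elastic fibre and collagen (−0.18, adjusted p = 0.0699). With both terms, lists that gained it were hedgehog signalling (0.18, adjusted p = 0.0204), immediate early and heat shock (−0.15, adjusted p = 0.00915) and circadian clock (−0.11, adjusted p = 0.0253). Over the 6 refits without one library, lists whose call changed at least once had medians of neuroendocrine −0.35 to 0.22, basal epithelium −1.99545 to 1.79, pan-endothelial −0.21 to −0.0471, lymphatic endothelium −0.24 to 0.00936, smooth muscle −0.75 to 0.0802, alveolar myofibroblast −0.19 to −0.0640, adventitial fibroblast −0.46 to −0.0368, pericyte −0.13 to −0.0145, mesothelium −0.33 to 0.11, macrophage and monocyte −0.23 to −0.0947, neutrophil −0.40 to 0.28, platelet and megakaryocyte 0.23 to 0.41, liver 0.20 to 1.93, fatty acid and phospholipid synthesis −0.14 to −0.0723, glucocorticoid-responsive −0.19 to −0.0748, hypoxia and glycolysis −0.20 to −0.0640, hedgehog signalling 0.0322 to 0.17, H3K4 methyltransferase complexes 0.0299 to 0.12, Hox genes 0.10 to 0.14, immediate early and heat shock −0.15 to −0.0129 and mitochondrially encoded mRNA −0.20 to −0.0820. The 9 lists that kept the call in all 6 had medians of alveolar type 1 −0.51 to −0.40, secretory airway −0.62 to −0.14, ciliated airway −0.61 to −0.22, capillary endothelium −0.32 to −0.20, cartilage 0.21 to 0.61, cell cycle 0.13 to 0.48, elastic fibre and collagen −0.23 to −0.12, interferon response −1.14 to −0.85 and lung liquid and ion transport −0.58 to −0.12. Genes called within 10 Mb of Kmt2c numbered 0 within 5, 10 and 20 Mb and without any one library, and 7 within 10 Mb with the title prefix as a term. Kmt2c stayed below 0 and short of the threshold in all alternatives, from −0.18 to −0.03.

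For the 99 named genes, 1372 of 1683 values under alternatives kept direction and side of the threshold, 217 lost the call, 94 gained it and 0 reversed; for the 45 lists these were 610 of 714, with 78 lost, 25 gained and 1 reversed. Changes of sign where neither value passed were counted as kept, 18 for genes (all in Kmt2d, Sftpc, Sftpa1 and Kdm6a) and 37 for lists. Only results with a call could lose it, so the 217 losses are all among the 28 named genes that passed. Likewise the 78 are all among the 18 lists past the threshold. Of the 28 named genes that passed, limma voom kept 2 and the sex-transcript term 8. Refits without wild type 2 or wild type 3 kept 0, whereas DESeq2 and the prefix term kept 28.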

Other observations

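Of the tests here, the comparison of interferon-response with macrophage genes and that of alveolar type 1 with type 2 genes were chosen after the results were seen. So were the correlations within title prefixes, the list values in other splits and the refit without wild type 1 and knockout 2. The genes of earlier lung development and the other terms tried beside the title prefix were not in the plan fixed before the data were examined.

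Several called genes fell outside the naming rule and were picked after their values were seen. Igfbp7, a secreted binding protein of vessels and mesenchyme, and Lgals3bp had the lowest adjusted p of all genes tested (0.0099 for both), going from 111 ± 11.1 to 62.8 ± 1.92 CPM for Igfbp7 and from 41.8 ± 3.44 to 21.4 ± 1.48 CPM for Lgals3bp. Ogn, an extracellular matrix proteoglycan, was at 272 ± 27.0 and 159 ± 8.65 CPM (log2 fold change −0.77, adjusted p = 0.016). The leptin receptor gene Lepr was lower by −0.76 and the pantetheinase gene Vnn1 by −0.86.

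Interferon-response genes had a median of −0.98 in knockout lungs. Fewer macrophages and monocytes would lower both lists alike if interferon-response transcripts came from these cells evenly and from no others. Interferon members lay below macrophage members by a mean of −0.92 (SE 0.17 over genes) on the log2 scale. That SE takes genes as independent and leaves out the spread between lungs, while the estimated correlation in the interferon list was 0.72. The comparison therefore cannot exclude a part played by these cells. One deviating library would move the list back toward 0, but the weakest median without any one library was −0.85. A difference in immune stimulation between litters or embryos stays open, since the labels give neither, and so does an effect of genotype.

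Alveolar type 1 genes had a median of −0.45, and of −0.41 without wild type 1 and knockout 2, the libraries with skeletal muscle transcripts. Less epithelium of every kind would lower type 2 genes as well, but type 1 members lay below type 2 members by a mean of −0.40 (SE 0.14 over genes). That SE takes genes as independent and leaves out the spread between lungs. The estimated correlation between genes was 0.49 in the type 1 list and 0.55 in the type 2 list. The 2 lists thus differed in point estimate, but this SE alone cannot decide. Centred on the mean of all libraries, the type 2 medians were −0.07 to 0.05 in wild-type libraries. In knockout libraries 1 to 3 they were −0.15, 0.004 and 0.20, with 11 members higher and 9 lower between genotypes. For the type 2 list, these values argue against a loss of every kind of epithelium as large as −0.45, but not against a smaller one. A smaller share of epithelium other than type 2 cells stays open, since the ciliated and secretory airway lists had medians of −0.47 and −0.33 (camera adjusted p = 2.1e-06 and 0.0014, but 0.63 for both with an estimated correlation, and as low as 8.8e-11 for the ciliated list in a split that mixes the genotypes). An earlier stage of maturation in the knockout embryos stays open. It was tried on 10 genes of earlier lung development (Lin28b, Hmga2, Igf2bp1, Igf2bp2, Igf2bp3, Mycn, Sox9, Id2, Bmp4 and Shh), 4 of them also members of fixed lists. All were higher in point estimate, with a median of 0.20 and an unadjusted camera p of 0.0017 with the preset correlation, which met the bound set for it. None was called, and camera p was 0.091 with an estimated correlation. Camera with the preset correlation also passed 1 to 20 lists in splits that mix the genotypes, which still hold part of any genotype difference. These 10 genes were not tried in those splits, so the pass does not decide the question. Exact embryo age and an effect of the genotype on maturation cannot be separated by this test, and the type 2 genes Sftpc and Sftpb did not pass in either direction.

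The title prefix as a term raised the calls from 70 to 625. Of the other 8 terms that split each genotype 2 to 1, 0 gave as many. The highest gave 234, also above 70, and the rest 0 to 51. Not every such term raised the calls, but with so few terms it cannot be told whether the prefix ranked first by chance. Whether libraries of one prefix share deviations in many genes cannot be told: the correlations over the 4 pairs of different genotype and the same prefix ran from −0.11 to 0.25, the lowest in a pair with wild type 1 and its skeletal muscle transcripts, while the split that follows the prefix had 1443 genes at an unadjusted p under 0.05, the most of the 9 splits that mix the genotypes (1069 in the next). The bound for excluding it was reset after these values were seen. What the prefix stands for (a litter, a mating or a day) stays open and no biological explanation was tested.

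The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 12 genes higher and 58 lower, each matched by 1 of the 10 splits, the real one, with 0 as the highest of the others in either direction; their counts at an unadjusted p under 0.05 ran from 334 to 1443, against 2043. For gene lists past the threshold, 3 of the 10 splits gave as many as the real 18, with 20 as the highest of the others, in the split of wild type 1, knockout 1 and knockout 2 from the rest. The split that follows the title prefix gave 0 genes and 9 lists, and the 1443 genes at an unadjusted p under 0.05 are from this split. Camera with a preset correlation thus passed 1 to 20 lists in splits that mix the genotypes. Each mixed split has 2 libraries of one genotype and 1 of the other on each side. Part of any genotype difference therefore remains between the sides, and the rest adds to the spread within them. Neither the list passes nor the 0 called genes of these splits measure what arises without a genotype effect. The interferon-response median had a size of 0.98 in the real split and at most 0.69 in the others, and the alveolar type 1 median 0.45 and at most 0.28. Each of these 2 lists passed in 4 of the 9 other splits, not all of them the same. The ciliated list passed in 5 of the others, with an adjusted p as low as 8.8e-11 against 2.1e-06 in the real split. The cell cycle list passed in 7, with 1.5e-11 as the lowest against 4.5e-06, so that neither list sets the genotypes apart from other splits.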
